A study of Mus musculus with 6 samples.

How the data were processed

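Messenger RNA was measured by bulk RNA sequencing in cerebella of C57BL/6J mice aged 40 weeks. There were 3 wild-type samples and 3 samples from mice with an SCA7 knock-in allele, in which the long Atxn7 allele encodes 140 glutamines and the short allele 5 glutamines. Per the labels' protocols, cerebella were snap-frozen, total RNA was extracted with a column kit, and stranded libraries of polyadenylated RNA were made with the Illumina TruSeq kit.

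The deposited values are raw counts of reads per Ensembl gene, which the authors made with HTSeq 0.6.1 per the submitters' processing notes. The same notes name bcl2fastq 2.17.1.14, TopHat2 2.0.14, Bowtie2 2.1.0 and the genome build mm10. The annotation release and the strand setting of the counting are not given in the sources used here, so counts of antisense genes and of genes that overlap on opposite strands are uncertain. The counts were not normalized by the authors as far as the values show: they are whole numbers that sum to between 34630391 and 49127673 per sample. Every count in the table was on a row with a gene identifier. Symbols, coordinates and transcript properties came from GENCODE M21 on the same build, which matched 48349 of 48709 identifiers. The 360 unmatched identifiers held 0.0503% of all counts.

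The tests were run in R 4.3.3. The comparison of knock-in with wild type used edgeR 4.0.16, with filterByExpr at its defaults (minimum count 10, minimum total count 15), TMM scaling, the quasi-likelihood F test on a model with the genotype alone, and Benjamini-Hochberg adjustment. A gene was called changed at an adjusted p at or under 0.05. The standard error of a log2 fold change was taken as its absolute value divided by the square root of its F statistic. CPM is the usual per-library scaling of a count, here by the TMM-scaled library size. Means are given with the SD over 3 samples.

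Gene lists were written from textbook markers before the data were examined, as were the test, its alternatives and the rule for named genes. The title of the series names the direction of Purkinje cell genes and was known when the lists were written. Of these lists, 40 were tested with camera from limma 3.58.1 at its preset correlation between genes of 0.01, with adjustment over the 40 lists, and each test was repeated with a correlation estimated from the data and with fry. A list needed at least 3 tested members. Members were counted after adjustment over all genes tested and after adjustment over the list alone.

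The rule for named genes took Atxn7, then the 8 higher and the 8 lower genes with the largest absolute log2 fold change among called genes with a mean CPM of at least 1 and no overlap between the groups. Gene models without a symbol, predicted genes and pseudogenes were passed over. It further took the 6 called members of the Purkinje cell list with the smallest adjusted p, up to 3 called members of every other list, and the most abundant member of a list without a called member. Some genes that the rule took are not reported here, although they count in their lists. Other genes named below were chosen after their values were seen.

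The labels give each sample a replicate number but do not state that the samples came from separate animals or that equal numbers pair them, so p-values measure the spread between these samples, which may in part be technical. Pairs of libraries within a group were compared with a chi-square test of their counts. The statistic per degree of freedom lay between 14.22 and 30.76, so every pair of libraries differed by more than the sampling noise and each was counted as 1 sample.

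The procedure was tested on simulated counts for this comparison, drawn with the means and depths of the real samples, in which 200 single genes were changed and a further list of 40 genes was lowered by 1.3-fold. The changed genes all had a mean CPM of at least 1. Of 16457 genes run, the test called 58% of the 100 genes changed by 1.5-fold and 91% of the 100 genes changed by 2-fold. Of its calls 10% were genes simulated as unchanged, a share above the adjusted p threshold of 0.05. Genes were drawn independently and without trends in GC content or length between libraries, so these shares may not hold for the real libraries.

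Alternatives covered the scaling, the filter, the test (DESeq2 1.42.0, limma-voom, voom with quality weights, robust estimation, a likelihood ratio test), the thresholds, the replicate number as a block and each sample left out in turn. Corrections for GC content and length, covariates for brainstem and choroid plexus markers and the removal of genes within 20 Mb of Atxn7 were added after the data were examined. The covariates are the mean log2 CPM of the list in each library. Processed pseudogenes were compared with protein-coding transcripts of GENCODE M21 by BLAST.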

Results

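Gene-level read counts were compared between 3 wild-type and 3 SCA7 knock-in samples of mouse cerebellum at 40 weeks. SCA7, spinocerebellar ataxia type 7, is caused by an expanded glutamine-coding repeat in Atxn7, a subunit gene of the SAGA transcriptional co-activator complex. The wild-type libraries held 49127673, 44090125 and 39528292 counts and the knock-in libraries 35562582, 39826478 and 34630391 counts, with at least 99.94% of each on the genes tested. The common biological coefficient of variation was 0.115. The comparison asks which cerebellar genes differ with the knock-in allele, and the title of the series names genes of Purkinje cell identity.

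Atxn7 (ENSMUSG00000021738, chromosome 14, 13961440 to 14107302, plus strand, mm10) had 25.9, 26.2 and 22.6 CPM in the wild-type samples and 22.4, 24.0 and 22.1 CPM in the knock-in samples. The log2 fold change was -0.12 ± 0.09 (SE, 3 against 3 samples) with an edgeR adjusted p of 0.52. Counts per gene do not separate the knock-in allele from the other allele, so they do not check the genotype labels.

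The Purkinje cell, mGluR1 signalling, Bergmann glia and astrocyte lists were among those lower in knock-in with the preset correlation, and the interferon-response list was among those higher. None of the 40 lists passed once the correlation was estimated (smallest adjusted p = 0.26 with an estimated correlation). Of 16699 genes tested, 318 changed at an edgeR adjusted p at or under 0.05, 213 lower and 105 higher. The lower genes were abundant and moved little, with a median log2 CPM of 6.38 and a median absolute log2 fold change of 0.55. The higher genes were less abundant, at a median log2 CPM of 2.94, and moved by a median of 0.81. In 23.8% of all tested genes the groups did not overlap, against 10% by chance for 3 against 3. With scaling by library size alone the split of calls was 190 lower and 323 higher. The number of called genes was 47, 89 and 78 without wild-type replicates 1, 2 and 3 and 39, 858 and 73 without knock-in replicates 1, 2 and 3, and was 3 with the brainstem marker level as a covariate.

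**Figure D1:**
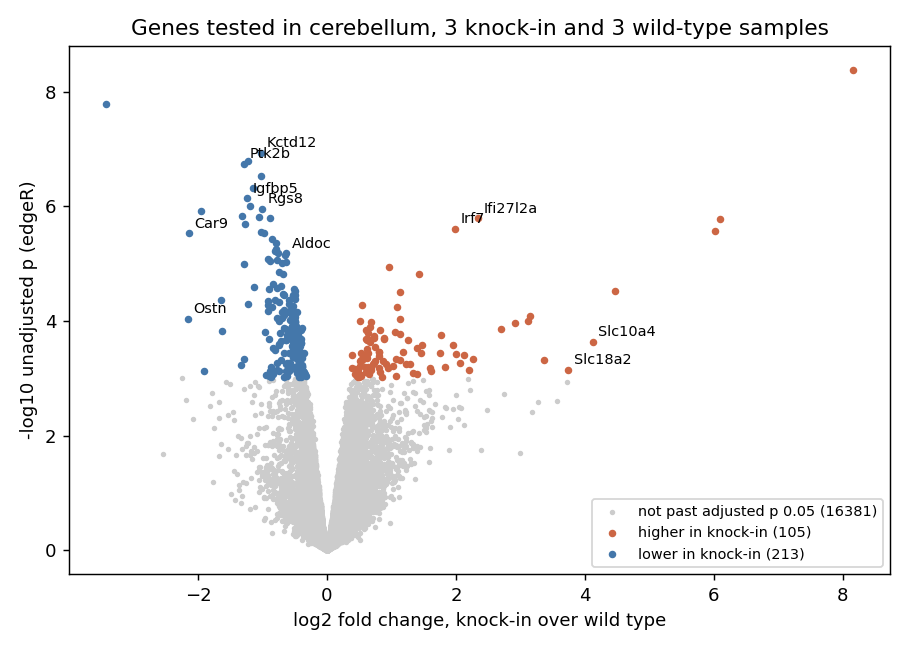
Each point is 1 of the tested genes, with the log2 fold change of knock-in over wild type on the x axis and the negative log10 of the unadjusted edgeR p on the y axis. The 105 higher genes are orange and the 213 lower genes blue.

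Among the 8 named genes with the largest decrease, Ptk2b, a calcium-dependent tyrosine kinase, fell from 22 ± 0.90 to 9.01 ± 0.81 CPM (mean ± SD, n = 3 each), a log2 fold change of -1.29 ± 0.11 with an edgeR adjusted p of 0.000607. Igfbp5, an insulin-like growth factor binding protein, fell from 208.1 to 88.3 CPM and Trabd2b, a Wnt-degrading metalloprotease, from 41.7 to 17.3 CPM. Car9, a carbonic anhydrase induced by hypoxia, fell from 6.40 to 1.45 CPM, and Ostn, which encodes the secreted peptide osteocrin, from 4.22 to 0.93 CPM. Chrnb4, a nicotinic receptor subunit, Muc3a and the noncoding RNA Mirt1 fell by 1.63, 1.29 and 1.65 on the log2 scale. Ptk2b lies at 66153257 to 66281052 on chromosome 14.

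Of 40 members of the Purkinje cell identity list 16 were lower and none higher, 33 were lower when adjusted over the list alone, and the median log2 fold change was -0.43. The camera adjusted p was 6.9e-35 with the preset correlation, and the adjusted p = 0.26 with an estimated correlation. Rgs8, a regulator of G protein signalling (chromosome 1, 153653025 to 153700323), fell from 2239.9 ± 199 to 1112.6 ± 136 CPM, a log2 fold change of -1.01 ± 0.10 (adjusted p 0.00175). Gng13, a G protein gamma subunit, changed by -0.81 ± 0.10. Doc2b, Arhgef33 and Stac fell by 0.69, 0.72 and 0.75 on the log2 scale. Calb1, the calcium buffer calbindin, fell from 1523.2 to 1078.0 CPM, Car8 from 2870.4 to 1961.6 CPM and Pcp4 from 390.1 to 251.0 CPM. Pcp2, another marker of these cells, had 444.6 ± 58.2 and 414.7 ± 69.8 CPM (adjusted p 0.73), Ebf1 a log2 fold change of 0.00 ± 0.08 and the transcription factor Foxp2 of 0.09 ± 0.12. With the brainstem marker level as a covariate, which is confounded in part with genotype, only 3 genes were called in all. Of the list 0 members were called, and its median was -0.35.

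**Figure D2:**
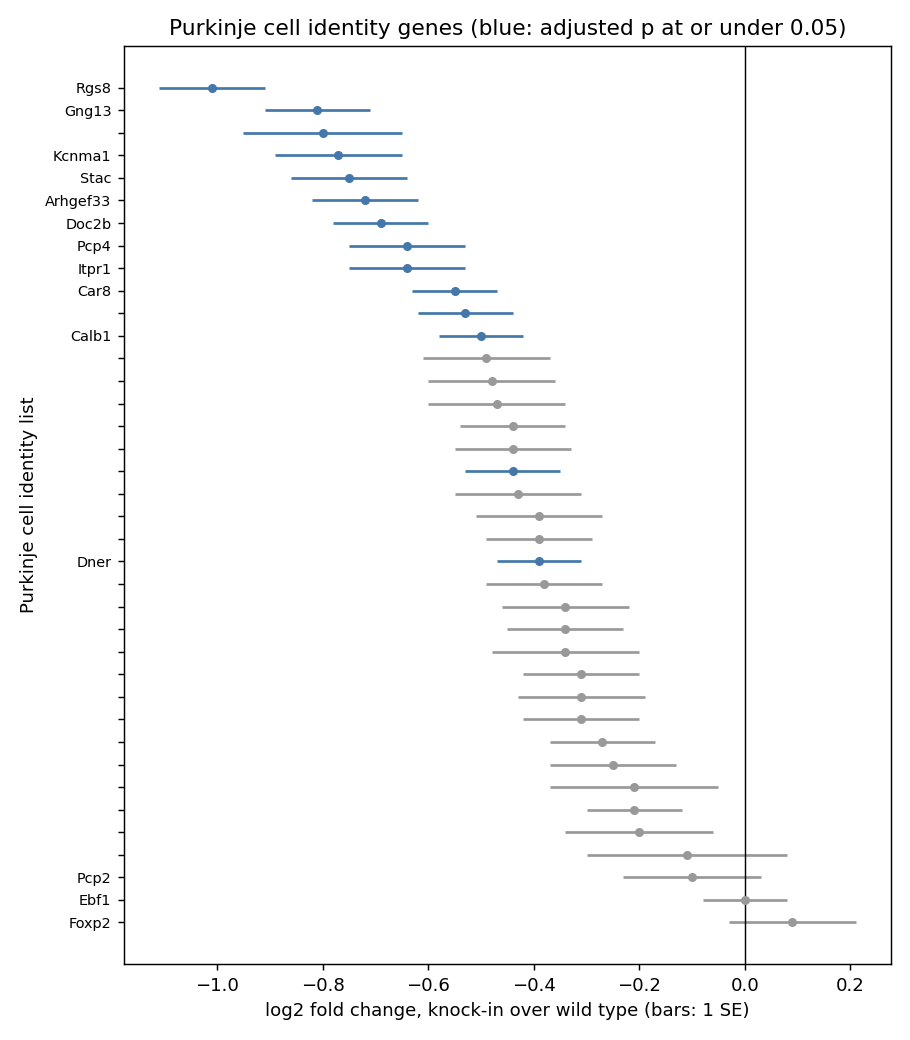
Points on the x axis are log2 fold changes of 38 of the 40 members of the Purkinje cell identity list, knock-in over wild type, 1 gene per line with symbols for those named in the text, and bars are 1 SE. The 14 drawn members past the threshold are blue, from Dner at -0.39 to Rgs8 at -1.01.

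Purkinje cells form alternating stripes with and without the antigen zebrin II, which is aldolase C. Of 10 zebrin-positive markers, 4 were lower (7 lower and 1 higher adjusted over the list alone), with a median of -0.43, a camera adjusted p of 2.4e-11 and an adjusted p = 0.26 with an estimated correlation. Kctd12, an auxiliary subunit of GABA-B receptors (chromosome 14, 102976581 to 102982637), fell from 313.9 ± 2.55 to 154.6 ± 12.7 CPM. Aldoc, which encodes aldolase C itself, fell from 2775.7 ± 147 to 1798.1 ± 123 CPM, and Plcb3, a phospholipase C, from 83.0 to 48.1 CPM. Of 5 zebrin-negative markers, 1 was lower, and 4 were lower adjusted over the list alone (median -0.34, camera adjusted p 0.00031, adjusted p = 0.36 with an estimated correlation). Counts of whole cerebellum do not assign these falls, that of Aldoc included, to Purkinje cells. The difference between the stripes was not tested.

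Of 22 genes of mGluR1 signalling, 6 were lower, and 18 when adjusted over the list alone, with a median of -0.34, a camera adjusted p of 9.3e-16 and an adjusted p = 0.26 with an estimated correlation. They share 13 members with other lists, among them Rgs8 and Plcb3. Of 38 calcium-handling genes 4 fell (15 lower and 3 higher adjusted over the list alone), led by Atp2a2, the calcium pump of the endoplasmic reticulum, from 2018.2 to 1258.1 CPM, and Itpr1, the IP3 receptor, from 5342.4 to 3433.6 CPM. Of 42 sodium and potassium channel genes 5 fell (13 lower and 2 higher adjusted over the list alone), including Kcnma1 by 0.77, Kcna6 by 0.48 and Kcnip4 by 0.46 on the log2 scale. The camera adjusted p was 4.3e-07 for the calcium-handling list and 2.6e-06 for the channel list. Both lists had an adjusted p = 0.41 with an estimated correlation. Of 31 glutamate receptor and scaffold genes 4 fell, among them Gria3, a subunit of AMPA receptors, from 160.1 to 118.3 CPM. Adjusted over the list alone 10 fell (camera adjusted p 2.2e-06, adjusted p = 0.47 with an estimated correlation). Of 22 GABA and glycine receptor genes, Gabbr2 and Gabbr1, both subunits of the GABA-B receptor, fell, by 0.53 and 0.39 on the log2 scale. Adjusted over the list alone 7 were lower (camera adjusted p 0.0018, adjusted p = 0.26 with an estimated correlation). Of 38 ataxia disease genes 4 fell, including Car8. Adjusted over that list alone 11 were lower and 1 higher (camera adjusted p 1.1e-05, adjusted p = 0.38 with an estimated correlation).

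Granule neurons, the most numerous neurons of the cerebellum, had 3 of 20 markers lower: Cbln3, Chn2 and Grm4, from 1778.0 to 1288.7, 936.7 to 652.9 and 321.0 to 192.0 CPM. Adjusted over the list alone 5 were lower and 1 higher, with a median of -0.09. The camera adjusted p was 0.0051 with the preset correlation, and the adjusted p = 0.59 with an estimated correlation. Of 16 interneuron markers none passed the threshold (4 lower adjusted over the list alone, median -0.13). The camera adjusted p of the list was 0.021 with the preset correlation, and the adjusted p = 0.36 with an estimated correlation. Unipolar brush and deep nuclear neurons had 0 of 8 called, 1 higher adjusted over the list alone, with Slc17a6 at 60.8 ± 13.8 and 69.0 ± 30.8 CPM.

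Of 15 astrocyte markers 3 were lower and 6 when adjusted over the list alone (median -0.19, camera adjusted p 3.8e-06, adjusted p = 0.36 with an estimated correlation): the gap junction gene Gja1, the water channel Aqp4 and the glutamate transporter Slc1a2, which fell by 0.49, 0.54 and 0.63 on the log2 scale. Of 11 markers of Bergmann glia, the astrocytes that surround Purkinje cells, A2m fell from 126.3 to 85.9 CPM and 6 were lower adjusted over the list alone (median -0.26, camera adjusted p 8.5e-07, adjusted p = 0.26 with an estimated correlation). In the reactive astrocyte list of 16 genes Serpina3n rose from 5.43 to 9.84 CPM and 2 were higher and 2 lower adjusted over the list alone. Of 22 myelin genes 4 were lower, including Tspan2 and Ugt8a, while 3 were higher and 7 lower adjusted over the list alone, with a median of -0.01. Among 12 precursor markers Olig1 rose from 53 to 87.7 CPM (2 higher adjusted over the list alone).

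Of 25 interferon-response genes 7 were higher and none lower, and 23 were higher when adjusted over the list alone. The median log2 fold change was 0.96, with a camera adjusted p of 4.6e-24, an adjusted p = 0.26 with an estimated correlation and one of 0.12 with fry. Irf7, the transcription factor that amplifies type I interferon, rose from 5.57 ± 1.42 to 22.3 ± 5.71 CPM, a log2 fold change of 1.99 ± 0.21 (adjusted p 0.00222, chromosome 7, 141262706 to 141266481). Usp18 rose from 2.77 to 10.8 CPM, Bst2 from 4.76 to 10.2 CPM, Ifi27 from 39.8 to 77.7 CPM and its paralogue Ifi27l2a from 1.81 to 9.21 CPM, and the similar sequences of the last pair make their counts uncertain. The mean log2 CPM of the list was 3.03, 3 and 2.65 in the wild-type libraries and 4.33, 3.73 and 3.43 in the knock-in libraries. Knock-in replicate 1 was also the highest in brainstem markers. Knock-in replicate 2, with a brainstem marker level of -0.13 that lay within the wild-type range, was still above every wild-type library in the interferon list. Complement and MHC class I genes had 0 of 14 called, 10 higher adjusted over the list alone and a median of 0.32 (camera adjusted p 1.1e-05, adjusted p = 0.26 with an estimated correlation). Homeostatic microglia markers had 0 of 16 called (4 higher and 1 lower adjusted over the list alone) and activated microglia markers 0 of 18, with medians of 0.06 and 0.08. With the brainstem marker level as a covariate, which is confounded in part with genotype, only 3 of 16699 genes were called in all. Among these were 0 interferon genes, a count that therefore says little about this list.

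The 8 named genes with the largest increase were limited to a mean CPM of at least 1 and to genes that are neither predicted genes nor pseudogenes, and Gm8420 at 8.16 and Hoxa7 at 4.47 on the log2 scale lie outside these limits. Among the 8, Slc18a2, the vesicular monoamine transporter, had 0.41, 1.46 and 0.26 CPM in wild type and 16.5, 1.56 and 10.4 CPM in knock-in (log2 fold change 3.74 ± 0.78, adjusted p 0.0436), and Slc10a4 had 3.68, 0.55 and 1.59 CPM in knock-in against at most 0.22 CPM. Dlk1 rose from 2.54 to 10.1 CPM, Gabrq from 1.3 to 5.42, and Arhgap36 from 0.95 to 4.60. Their knock-in values were uneven and lowest in replicate 2. They were 15.1, 5.65 and 9.58 CPM for Dlk1, 8.66, 2.38 and 5.21 for Gabrq and 8.09, 2.44 and 3.26 for Arhgap36. The neuropeptide gene Gal rose from 0.42 to 1.44 CPM, the only higher one of 20 neuropeptide genes (8 higher and 4 lower adjusted over the list alone). It had 1.89, 0.85 and 1.56 CPM in the knock-in libraries. Among 7 tested brainstem markers none was called over all genes and 5 were higher adjusted over the list alone, with a median of 2.99 and a camera adjusted p of 0.0014 (adjusted p = 0.47 with an estimated correlation). Their mean log2 CPM was -1.01, 0.09 and -1.33 in wild type and 2.50, -0.13 and 1.49 in knock-in, so knock-in replicate 2 lay within the wild-type range. Choroid plexus markers varied within both groups: Ttr, the transthyretin of that epithelium, had 468.2, 452.8 and 1778 CPM in wild type and 238.6, 2.59 and 1244 CPM in knock-in, and 0 of 14 markers were called (median -1.08, camera adjusted p 7.4e-06, adjusted p = 0.51 with an estimated correlation).

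**Figure D3:**
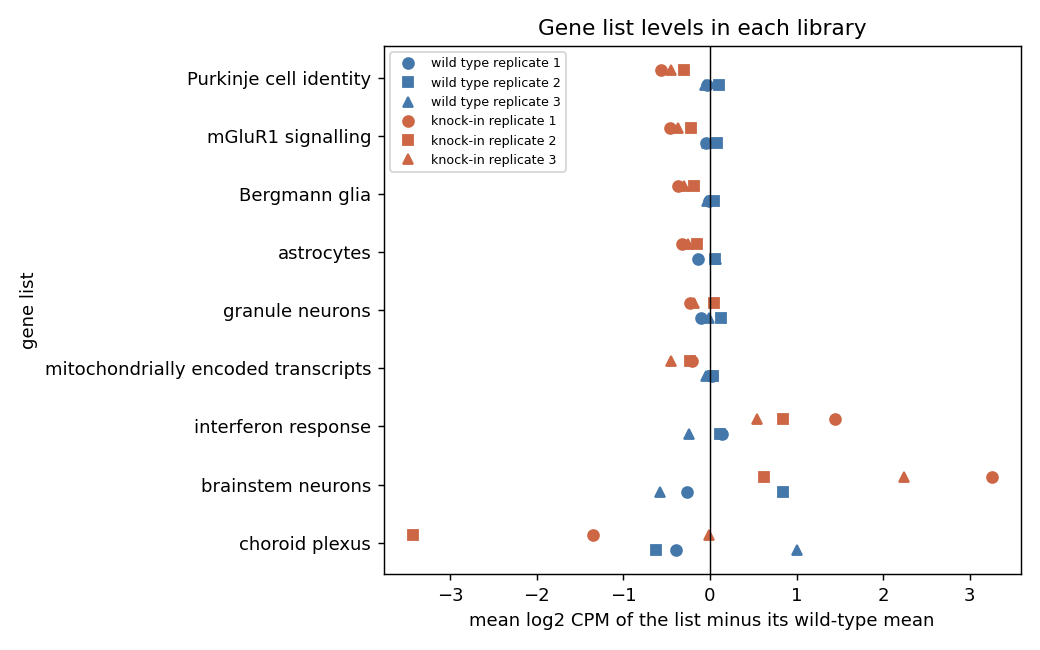
Points give the mean log2 CPM of each list in each library after subtraction of the wild-type mean, with wild type in blue, knock-in in orange and symbols for the replicates. Purkinje levels are below all wild-type libraries in the 3 knock-in libraries, while brainstem and choroid plexus levels differ widely between libraries of 1 group.

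The mitochondrially encoded transcripts had 5 of 12 lower, 7 adjusted over the list alone, with a median of -0.40, a camera adjusted p of 2.6e-06 and an adjusted p = 0.36 with an estimated correlation. The transcript mt-Co1 fell from 6660.2 ± 226 to 4993.6 ± 467 CPM, and mt-Nd1 and mt-Nd2 fell by 0.39 and 0.48 on the log2 scale. With GC and length offsets, chosen after the data were seen, 1 of the 12 was lower, and mt-Co1 and mt-Nd2 were no longer called, at log2 fold changes of -0.43 and -0.55 (adjusted p 0.069 and 0.056). They made up 2.73%, 2.71% and 2.65% of counts in wild type and 2.29%, 2.26% and 2.05% in knock-in. The 43 nuclear oxidative phosphorylation genes had no call and a median of 0.05, with Atp5b at 2099.6 and 2107.9 CPM. The 49 cytosolic ribosomal protein genes had no call, a median of 0.16 and a camera adjusted p of 4.9e-05, with an adjusted p = 0.59 with an estimated correlation. Across genes, which are not independent replicates, log2 fold changes had a Spearman rho of 0.37 with GC content and -0.29 with exon length. Single libraries stood apart. Relative to the mean over all libraries, rho with GC content was -0.63, 0.07 and 0.04 in wild type and 0, 0.30 and 0.35 in knock-in. With exon length it was 0.16, 0.36 and 0 in wild type and -0.09, 0.18 and -0.53 in knock-in.

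No member was called in the remaining lists. Medians were 0.03 for 24 ataxin-7 and SAGA complex genes, 0.01 for 31 proteasome genes, 0.03 for 25 autophagy and lysosome genes, 0.05 for 17 p53 targets and -0.03 for 21 chaperone genes, 1 of which was higher adjusted over the list alone. The unfolded protein response list had a median of -0.14 over 21 genes (2 lower adjusted over the list alone, camera adjusted p 0.0024, adjusted p = 0.44 with an estimated correlation) and the immediate early genes one of 0.29 over 20 (camera adjusted p 0.026, adjusted p = 0.62 with an estimated correlation). Medians were -0.11 for 24 cholesterol synthesis genes, -0.07 for 16 clock genes, -0.06 for 13 endothelial and pericyte markers, -0.03 for 9 meningeal, -0.22 for 5 blood and 0.34 for 7 forebrain markers. Adjusted over the list alone, 1 endothelial and 1 blood marker were lower, and 2 forebrain markers were higher and 1 lower. The 22 lists without a called gene held 418 tested members, of which 100 had an unadjusted edgeR p under 0.05 and 34 were called by DESeq2. With the preset correlation 21 of the 40 lists passed the threshold, 16 lower and 5 higher. With an estimated correlation 0 did, with 7 at an unadjusted p under 0.05, and with fry 1 did, the zebrin-positive list at an adjusted p of 0.038.

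Within 20 Mb of Atxn7, 9 of 162 other tested genes were called (5.56%), 6 higher and 3 lower, against 1.87% of the other tested genes (two-sided Fisher's exact p 0.0039, a region chosen after its values were seen). Within 5 Mb it was 2 of 23 (p 0.07). Among the 9 were Il3ra at 14346275 to 14356011 (0.46 and 1.29 CPM), Fam107a at 8296274 to 8318023 (1070 and 728 CPM) and Kcnma1. Another was Synpr, a synaptic vesicle protein, at 13284780 to 13616340 (123 and 161 CPM). The predicted genes Gm3383 and Gm10406 also counted among the 9, with few counts. They had 0.0223 and 0.0474 CPM in wild type and 0.266 and 0.428 CPM in knock-in.

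**Figure D4:**
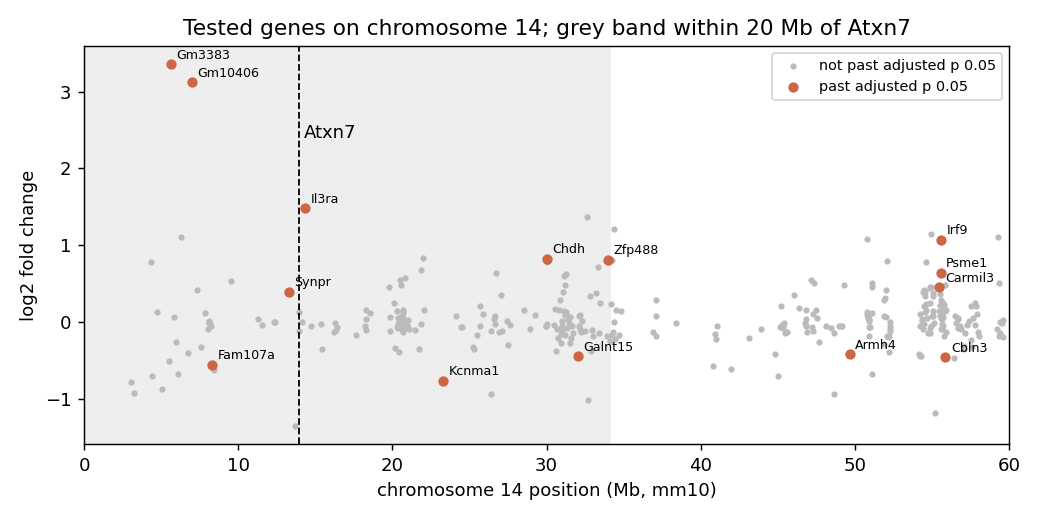
Points are tested genes on the proximal part of chromosome 14, by position in Mb (mm10) and log2 fold change of knock-in over wild type, with called genes in orange. The dashed line marks Atxn7 and the grey band spans 20 Mb on either side, ending at the chromosome start on the left, and holds 9 called genes.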

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

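Corrections for GC content and length, the marker covariates and the removal of genes near Atxn7 were chosen after the data were seen. All 55 named genes that were called kept their direction under the alternatives run for each, at most 23, and 1, Ptk2b, was called under all of them. Atxn7 was past the threshold under none of its alternatives, with log2 fold changes from -0.21 to -0.04, and it was not tested where genes near it were removed. Against 318 called genes (105 higher, 213 lower) and 16 lower Purkinje members, library size alone gave 513 (323 higher), no filter 1303 (695, 608; 30 Purkinje members), DESeq2 934 (413, 521; 25), voom with quality weights 746 (273, 473; 26) and the likelihood ratio test 948 (456, 492). An adjusted p threshold of 0.1 gave 721 (302, 419), one of 0.01 gave 42 (7, 35; 4 Purkinje members), and a minimum absolute log2 fold change of 0.5 left 135 lower genes. GC and length offsets gave 763 (244, 519; 29), and with the replicate block 1570 (629, 941; 34). The choroid plexus covariate gave 1469 (475, 994; 25) and the brainstem covariate 3 (1 higher, 2 lower, 0 Purkinje members). Leaving out 1 sample gave 39 to 858 called genes, 7 to 348 higher, 32 to 510 lower and 2 to 26 Purkinje members, the lowest counts without knock-in replicate 1 and the highest without knock-in replicate 2. The Purkinje list had an adjusted p of 0.26 with an estimated correlation and 0.056 with fry. The direction of the brainstem list reversed with its own level as covariate (adjusted p 0.76), and that of the immediate early genes without knock-in replicate 2 (0.71, the other samples left out giving down to 0.00033) and with the choroid plexus covariate (0.16). Fewer samples leave fewer residual degrees of freedom, which does not account for the rise to 858 without knock-in replicate 2. On the second principal component of log2 CPM that library lay at -38.3, and every other library between -3.6 and 18. The brainstem covariate is confounded in part with genotype. Beyond this the cause was not tested. At this depth 58% of simulated 1.5-fold changes were called, in genes with a mean CPM of at least 1.

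Whether equal replicate numbers pair the samples was not settled. Deviations from the group means of samples with equal numbers had correlations of 0, 0.17 and 0.32 for numbers 1, 2 and 3. Wild-type replicates 2 and 3 correlated best with their own number, while wild-type replicate 1 correlated best with knock-in replicate 2, at 0.1. With 3 samples per group the deviations are tied to one another, so these correlations cannot decide it. The replicate block gave 2034 called genes, 1026 higher and 1008 lower, with 34 Purkinje members lower.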

Other observations

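The tests in this part were chosen after the results were seen, except the count of other splits of the samples. Hoxa7, a homeobox gene of the posterior body axis, had 0, 1 and 1 counts in wild type and 16, 15 and 15 counts in knock-in (edgeR adjusted p 0.011). Hotairm1, a noncoding RNA of the same cluster whose strand assignment is uncertain here, was also called. Hoxb6, too low to be tested, had 0 counts in each wild-type library and 8 in each knock-in library. Over all annotated Hox genes the counts were 24, 16 and 100 in wild type and 102, 43 and 88 in knock-in, so the groups overlapped, and Hoxb3 had 0, 1 and 14 counts in wild type and 9, 0 and 10 in knock-in (adjusted p 0.85).

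Of the 10 splits of the 6 samples into 3 and 3, the real one gave 318 called genes and the highest of the others 1. With 10 splits a share under 0.05 cannot be reached (1 of 10 gave as many). Every other split mixes both genotypes within its groups. Any difference between the genotype groups, a technical one included, then adds to the spread and holds calls down, so the contrast cannot tell these apart.

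Of 40 Purkinje cell identity genes 16 were called lower in knock-in, 2 without knock-in replicate 1 and 0 with the brainstem covariate. The median log2 fold changes were -0.43, -0.37 and -0.35, and over all genes these settings gave 318, 39 and 3 calls. The list had an adjusted p = 0.26 with an estimated correlation and 0.056 with fry. Offsets for GC content and length left the list median at -0.45, which argues against that trend as the whole source. Relative to granule neuron markers the mean of the list differed by -0.31 on the log2 scale with no overlap between groups, which argues against dilution by other tissue alone. The log2 fold changes of 14 transcripts restricted to Purkinje cells, from Rgs8 at -1.01 to Pcp2 at -0.10, differed among themselves (chi-square p across genes 8.4e-11, and 1.1e-06 without Rgs8), which argues against an equal loss of all Purkinje cells as the only source. The test takes the genes as independent and their SEs as known, so its p may be too small. GC and length offsets moved some values, Skor2 from -0.11 to -0.45 and Itpka from -0.31 to -0.58 (chi-square p with the offsets 1.2e-14). A part from cell loss and an effect of the allele within the cells stay open and were not tested.

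Of 7 tested brainstem markers none was called. Dbh and Slc6a2 were highest in knock-in replicates 1 and 3, while Th had 13.4, 15.4 and 14.6 CPM in wild type and 16, 7.36 and 14.8 CPM in knock-in. Across the 6 libraries the noradrenergic markers Dbh, Slc6a2 and Th had a Spearman rho of 0.6 with serotonergic plus cholinergic markers (exact permutation p 0.24, adjusted over 2 relations 0.24) and a Pearson r of log2 CPM of 0.90 (p 0.026, adjusted 0.035), which was -0.43 without the 2 libraries farthest from the median and so rests on those. Without Th, a choice made after its values were seen, rho was 1 (p 0.0028, adjusted 0.0056) and r 0.80 (p 0.035, adjusted 0.035), or 0.88 without the 2 farthest libraries. Th did not follow Dbh and Slc6a2: in wild-type replicate 3 it had 14.65 CPM, with Dbh at 0 and Slc6a2 at 0.13 CPM. In wild type the sum with Th is mostly Th, so the relation with Th does not decide. The relation without Th was chosen after its values were seen. Brainstem tissue carried over in dissection and an effect of the allele on these genes therefore cannot be told apart here.

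Of genes within 20 Mb of Atxn7 5.56% were called, against at most 5.08% in 260 other windows. Within 10 Mb it was 7.5%, against at most 7.14% in 228. These windows lay on chromosomes other than 14, were centred every 10 Mb and overlap, so they are not that many separate comparisons. The called genes at both distances include Gm3383 and Gm10406, which had few counts. The region was chosen after its calls were seen and the margins are small, so chance clustering stays open. The 3 called processed pseudogenes, on chromosomes 1 and 2, have 2 closest coding genes, Rpl15 and Pdhb, both within 20 Mb of Atxn7. So are 3 of the 100 closest coding genes that have no called pseudogene (one-sided Fisher's exact p 0.0019). Gm8420 had 2, 0 and 0 counts in wild type and 231, 179 and 185 in knock-in, and is 96.6% identical to Rpl15, as Gm14094 is 94.6% identical, while Gm6123 is 97.0% identical to Pdhb. A further 6 pseudogenes with the closest gene within 20 Mb of Atxn7 were not called. Among them Gm13688, 93.1% identical to Rpl15, had 84, 54 and 41 counts in wild type and 60, 54 and 41 in knock-in (edgeR adjusted p 0.98). Rpl15 and Pdhb had log2 fold changes of 0.16 ± 0.09 and -0.03 ± 0.08 (highest upper 95% bound 0.33), against at least 6.01 for the called copies, which argues against a changed level of the parent genes as the source of the called pseudogene counts. With only 2 parent genes, noticed before the test, a segment of another strain kept around the knock-in allele stays open, and for the called neighbours it and an effect of the allele cannot be told apart.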
